A study of Mus musculus with 2 samples.

How the data were processed

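Total RNA was taken from the liver of mouse embryos of the B6NCrl strain at embryonic day 16.5. Libraries of its part above 200 nt were sequenced. The 2 libraries form 1 group, E16.5 liver, with 2 biological replicates, both from pools of male and female embryos. The labels give 41 embryos for the replicate 2 pool and no number for replicate 1. Per the labels, RNA was extracted with the mirVana kit, RNA above 200 nt was kept, 10 ng went into each library, the SMARTer ultra-low input kit was used and spike-in RNA was added. How evenly the kit captured different kinds of RNA was not tested. Levels of histone and structural RNA may therefore not be those of the tissue. Both libraries carry the same donor identifier. The labels name no strand-specific step, so reads of overlapping and antisense genes were treated as not told apart.

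For each library the authors deposited a gene table of 69691 rows and a transcript table of 129984 rows, quantified on mouse assembly mm10 with GENCODE annotation release M4, per the file headers and the text deposited beside the tables. That text says that the values derive from alignments to the transcriptome. The column names are those of the program RSEM, whose version, like the aligner, is not given in the sources used here. The expected counts, per the file headers, are estimated counts that need not be whole, as reads shared by several transcripts are divided among them. The deposited TPM values are scaled to a fixed sum over all rows of a table, spike-ins included, and the deposited posterior mean TPM is a second estimate of the same quantity. The deposited FPKM values were read but entered no result. The deposited percent columns give each transcript's share of its gene, and the shares used here were recomputed from TPM. The deposited TPM intervals carry no stated level. For the most abundant genes the TPM lay outside its own interval, so intervals were compared only with each other between libraries. Expected counts within 0.01 of a whole number were taken as whole. The effective length of a transcript in the tables was its length less 99 nt, so transcripts shorter than that held no counts, and the TPM of a transcript only slightly longer rests on few reads.

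The gene table held 43346 Ensembl genes, 96 ERCC spike-ins, 1 phiX row and 26248 numbered rows with a median length of 73 nt that no header explains. Gene symbols, biotypes and coordinates came from GENCODE release M21, whose assembly, GRCm38, is the build called mm10. IDs were matched without their version. Of the Ensembl genes, 42462 (98.0%) had a match and 884 had none. Coordinates below are of that release, from 1.

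Expected counts summed to 44477766 in replicate 1 and 48820712 in replicate 2, of which 43364573 and 47263435 lay on Ensembl genes. A gene of median effective length would need 0.068 TPM in replicate 1 and 0.063 TPM in replicate 2 to reach 3 expected counts, the limit taken for a gene with none. Reads carried no molecular identifiers, so such limits and all counting intervals cover counting error only.

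The design holds no comparison between conditions, and the comparison of replicates sets 1 library against 1, so no p-value is given. Levels are the mean and SD of the 2 libraries. A gene was called expressed at 1 TPM or more in both libraries. A fixed set of 47 gene lists, by cell type and pathway of the fetal liver, of blood, of neighbouring tissues and of RNA quality, was described by the median TPM of its members in each library. The replicates were compared by Pearson and Spearman correlation across genes of log2(TPM + 1), and by the log2 ratio of TPM + 1, replicate 2 over replicate 1, centred on the median of genes with a mean expected count of 100 or more. For lists with 5 or more members at a mean expected count of 10 or more, the median ratio was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. The percentile describes these 2 libraries, and genes of a list are not independent. The lists, thresholds and alternatives were fixed before the data were examined.

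The genes named are those of a rule fixed at the same time. It takes the 15 genes with the highest mean TPM, the 3 highest and the lowest member of each list (4 highest in transcription factor and cell type lists), the 8 genes with the largest centred ratio in each direction among genes with a symbol, a mean expected count of 100 or more and TPM intervals that did not overlap, the 6 most abundant genes whose leading transcript differed between libraries or held under 50% of the gene, the genes of the fixed ratios and the sex-linked list. Where several members of a list stood at 0, the lowest is given as their shared value. List members missing from the tables were counted and not named. Some genes that the rule selects are left out of the text, and the values of their lists still include them.

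Alternatives comprised other detection thresholds and pseudocounts, the posterior mean TPM, TPM rescaled over annotated nuclear genes, TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0 on expected counts rounded to whole numbers (R 4.3.3), scaling to the spike-ins, other count filters, and each replicate alone. Other steps used python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

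The comparison of replicates was tested on simulated data drawn for the 43346 genes with the libraries' means and sizes and an assumed biological coefficient of variation of 0.1. With a pseudocount of 1, it recovered 85 of 100 genes changed 3-fold and 95 of 100 genes changed 4-fold, and it passed 0 of 11818 unchanged genes. A planted list of 20 genes shifted by 0.3 on the log2 scale had a median of 0.33 at the 100th percentile of random lists, and an unshifted list of 20 genes stood at the 44.4th. The simulated genes varied independently, so the percentile was not checked for lists whose genes vary together.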

Results

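The series describes the transcriptome of the mouse fetal liver at embryonic day 16.5, when the organ forms blood cells and its hepatocytes express plasma protein genes. It holds 1 group of 2 biological replicates, each a library from pooled livers of both sexes, with 44477766 expected counts in replicate 1 and 48820712 in replicate 2. The labels set no second condition, so the question the design allows is which genes the tissue expressed, at what level, and how far the 2 libraries differed. Values are the mean ± SD of the 2 libraries (n = 2) as TPM (a gene's abundance relative to all transcripts of its library) unless a library is named.

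Globin genes of red cells were the most abundant. The 4 adult globin genes together carried 34.4% ± 0.586 (SD, n = 2) of all TPM and 16.1% of expected counts, and protein-coding genes outside the globin, histone, ribosomal protein and mitochondrial classes carried 48.2% ± 0.324 of TPM. The alpha globin genes Hba-a2, at 144164 ± 977 TPM, and Hba-a1, at 64195 ± 370 TPM, and the beta globin genes Hbb-bs, at 74013 ± 1703 TPM, and Hbb-bt, at 61676 ± 2807 TPM, were the 4 most abundant genes. The members of each pair are near-identical, so the division between Hba-a1 and Hba-a2 and between Hbb-bs and Hbb-bt is uncertain and their sums are used. Alpha globins held 60.5% ± 0.640 of globin TPM (SD, n = 2). With all copies summed, alpha globins were above beta globins in replicate 1 (60.1%), in replicate 2 (61.0%) and with counts in place of TPM (55.1%). Counting a single copy of each pair leaves out reads and depends on the uncertain division, so it does not decide that order. With Hba-a1 and Hbb-bs alone as the adult globins, alpha globins held 46.4%. The embryonic globins held 0.047% ± 0.0001 (0.118% with those single copies), with Hbb-y at 95.4 ± 1.03, Hba-x at 40.3 ± 1.99, Hbb-bh1 at 24.8 ± 4.46, Hbb-bh0 at 2.25 ± 0.955 and Hbb-bh2 at 0.16 ± 0.13 TPM. The last 2 rest on 4 expected counts or fewer in each library. The median member stood at 69104 ± 1036 TPM in the adult and 24.8 ± 4.46 in the embryonic list. Hba-a2 (ENSMUSG00000069917.7) spans chromosome 11, 32296489 to 32297298, and Hba-a1 (ENSMUSG00000069919.7) chromosome 11, 32283511 to 32284465, both on the plus strand. Hbb-bs (ENSMUSG00000052305.5) lies at chromosome 7, 103826534 to 103828096, and Hbb-bt (ENSMUSG00000073940.3) at chromosome 7, 103812524 to 103813996, on the minus strand.

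The next most abundant genes included those of secreted products of hepatocytes. Trf, which encodes the iron carrier transferrin, stood at 18208 ± 2307 TPM and Afp, the fetal plasma protein alpha-fetoprotein, at 13648 ± 27.0 TPM. Alb, which encodes albumin, stood at 7052 ± 796 TPM, so that the ratio of Afp to Alb was 1.95 ± 0.224 (SD, n = 2). The lipoprotein genes Apoa2, above Alb at 7706 ± 43.3, and Apoa1, at 6250 ± 356 TPM, were also among the 15 highest, as was the metallothionein gene Mt1, at 5657 ± 97 TPM. Trf (ENSMUSG00000032554.11) lies on chromosome 9, 103204001 to 103230444. Afp (ENSMUSG00000054932.3) and Alb (ENSMUSG00000029368.9) neighbour each other on chromosome 5, at 90490737 to 90508907 and 90460897 to 90476602. Apoa2 (ENSMUSG00000005681.8) lies on chromosome 1, 171225054 to 171226379, Apoa1 (ENSMUSG00000032083.8) on chromosome 9, 46228580 to 46230466, and Mt1 (ENSMUSG00000031765.7) on chromosome 8, 94179082 to 94180327. The other genes among the 15 highest were noncoding or mitochondrial. Rn7s1 and Rn7s2, RNA components of the signal recognition particle, stood at 10434 ± 1047 and 10434 ± 1046 TPM and share their reads. The mitochondrial gene mt-Atp6, at 5523 ± 319 TPM, and the unprocessed pseudogene Gm28437, at 5748 ± 380 TPM, had expected counts that were not whole, so part of their reads was divided with other genes. The TPM of Gm22133, an annotated microRNA gene of 109 nt, was 5510 ± 279, but it rests on 2236 and 2596 expected counts over an effective length of 10 nt and is not comparable with that of longer genes. Gm22133 lies within the ferritin gene Ftl1 on the same strand. Both had counts that were not whole, so the reads of Gm22133 may be shared with Ftl1. The 10 highest genes held 41.5% of TPM in replicate 1 and 40.8% in replicate 2.

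At 1 TPM or more in both libraries, 12097 genes were expressed, of which 11201 were protein coding. Replicate 1 had 12342 such genes and replicate 2 had 12598. At 100 TPM or more in both libraries there were 917 genes, and at 1000 TPM or more 61. Genes given below as 0 TPM had no counts in either library, which at 3 counts allows from 0.029 TPM for Nkx2-1 to 0.235 for Hist1h4m in replicate 1. This limit takes no account of reads divided between copies, and the deposited interval of Hist1h4m, whose copies share reads, reached 1.24 TPM. Such genes are not shown to be absent, and other members of the same lists were at 0 in some cases. List medians depend on the division by transcript length, and as TMM-scaled counts 34 of the 46 medians above 0 differed from TPM by over 1.5 times.

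Plasma protein genes were expressed almost throughout. All 18 plasma transport proteins were at 1 TPM or more in both libraries and 15 at 100 TPM or more, with a median of 965 ± 96.0 TPM (SD, n = 2). Hrg, which encodes histidine-rich glycoprotein, was the lowest at 6.76 ± 1.54. Of 13 genes of apolipoproteins and lipid export, 11 reached 1 TPM in both libraries, with Apoe at 3475 ± 291 and Apoa5 lowest at 0.49 ± 0.11 TPM, and the list's median was 595 ± 3.83 TPM. The 17 coagulation factors and inhibitors were all at 1 TPM or more, with a median of 199 ± 14.0. The fibrinogen chains Fga, at 1303 ± 61.0, and Fgg, at 1159 ± 69.3, and the antithrombin gene Serpinc1, at 1165 ± 79.6, led, and F9, which encodes coagulation factor IX, was lowest at 3.79 ± 0.127. Complement and acute phase genes were lower, with a median of 37.8 ± 0.134 TPM. C3 stood at 490 ± 67.3, the factor B gene Cfb at 375 ± 52.0 and the factor I gene Cfi at 267 ± 10.2, and Saa2, an acute phase gene, at 0.

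**Figure D1:**
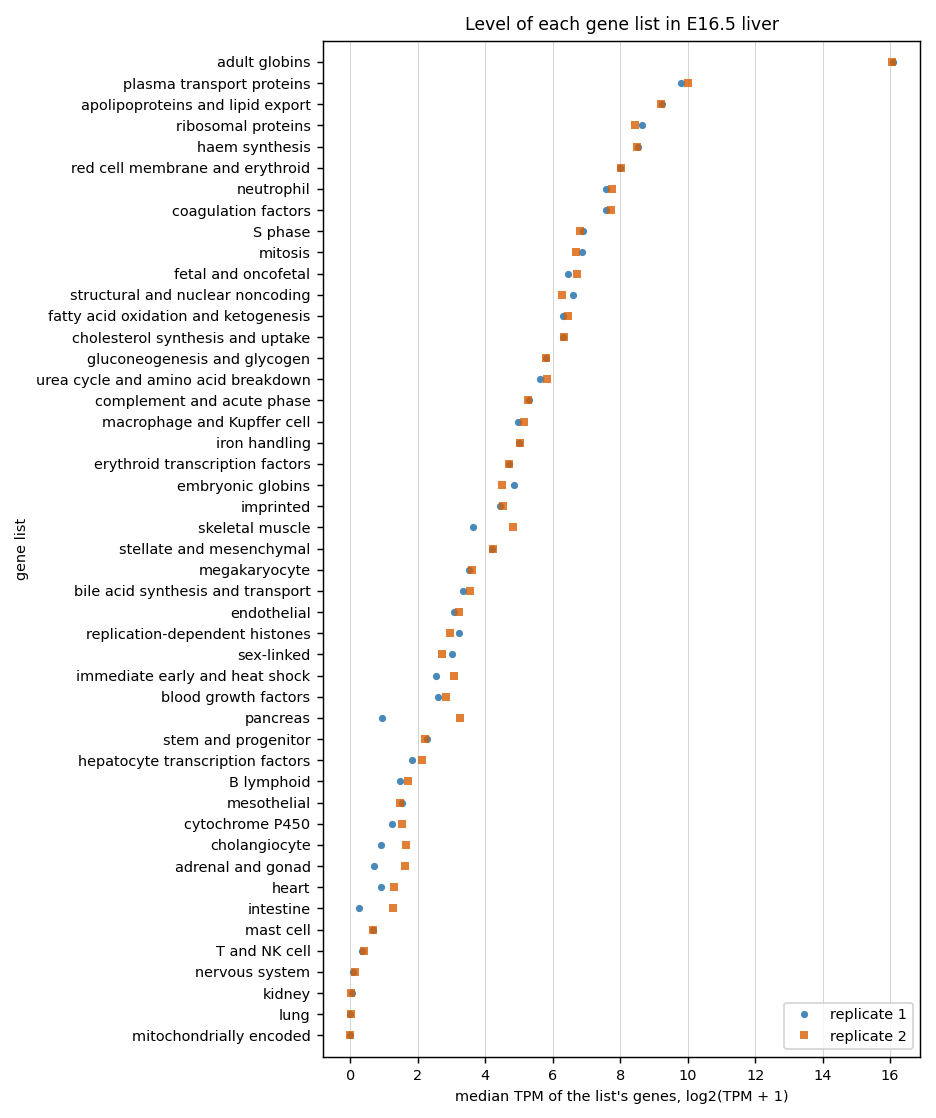
Median TPM of the genes of each of the 47 lists, as log2(TPM + 1), with a point for each library. Adult globins lie highest, with plasma transport proteins (965 TPM) and apolipoproteins (595 TPM) next, and the lung, kidney and nervous system lists lie near 0.

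Metabolic lists divided by pathway. Fatty acid oxidation and ketogenesis genes had a median of 81.6 ± 5.62 TPM, with Acadl at 156 ± 4.75, Acadm at 125 ± 13.7 and the coactivator gene Ppargc1a at 3.46 ± 0.233. Cholesterol synthesis genes had a median of 78.6 ± 1.66, with Fdps at 319 ± 0.580 and Hmgcs1 at 189 ± 5.59 TPM. In the urea cycle and amino acid list (median 52.0 ± 5.61 TPM), Ass1 stood at 385 ± 47.5, Glul at 125 ± 1.63, Hpd at 105 ± 10.8 and the tryptophan dioxygenase gene Tdo2 at 0.045 ± 0.0071. In the gluconeogenesis and glycogen list (median 54.3 ± 0.202), Pygl stood at 120 ± 12.2 and Fbp1 at 111 ± 26.5 TPM, while G6pc, the glucose-6-phosphatase gene, stood at 0.18 ± 0.071. 3 of its 10 members were below 1 TPM in both libraries. Bile acid genes had a median of 9.84 ± 1.15 TPM, with Hsd3b7 at 67.8 ± 4.09, Slc27a5 at 30.3 ± 1.80, the uptake transporter Slc10a1 at 28.7 ± 7.43 and Cyp7b1 at 0.23 ± 0.17. Cytochrome P450 genes had a median of 1.63 ± 0.385 TPM (SD, n = 2), and 5 of 12 listed members were below 1 TPM in both libraries. Their reductase Por stood at 43.8 ± 3.57, Cyp3a11 at 40.4 ± 0.990, Cyp2d22 at 11.2 ± 1.30 and Cyp2c29 at 0.

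Hepatocyte transcription factor genes were low, with a median of 2.93 ± 0.580 TPM, and 12 of 15 were at 1 TPM or more in both libraries. Foxa3 stood at 55.0 ± 1.35, Hnf4a at 17.5 ± 1.34, Cebpa at 6.38 ± 1.24, Prox1 at 6.28 ± 0.460 and Cebpb at 0.47 ± 0.085 TPM. Fetal and oncofetal genes had a median of 95.5 ± 13.1, from Afp down to Hmga2 at 1.04 ± 0.134. The imprinted growth factor Igf2 stood at 568 ± 51.7 and the noncoding H19 at 547 ± 59.8, a ratio of H19 to Igf2 of 0.963 ± 0.018 (SD, n = 2). With counts in place of TPM the ratio was 1.40, which turns which of them is higher. Of 22 imprinted genes 19 reached 1 TPM in both libraries. The third highest was Dlk1, at 416 ± 12.6, the lowest Rtl1, at 0.58 ± 0.021, and the median 21.2 ± 0.898. Among iron genes (median 31.2 ± 0.336), the ferritin chains Ftl1, at 5400 ± 63.1, and Fth1, at 3368 ± 138, and the exporter Slc40a1, at 157 ± 0.573, were highest, and Hamp2 stood at 0. Besides Igf2, the blood growth factor list (median 5.60 ± 0.718) held Cxcl12 at 51.4 ± 1.79 and the erythropoietin gene Epo lowest at 0.90 ± 0.26 TPM.

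Erythroid genes other than globins were high as a group. The red cell membrane and erythroid list had a median of 254 ± 4.72 TPM, and all 17 members found were at 10 TPM or more in both libraries. Car2 stood at 1950 ± 267, the anion exchanger Slc4a1 at 973 ± 37.4, Rhd at 470 ± 20.9 and Car1 lowest at 31.4 ± 3.73. Haem synthesis genes had a median of 363 ± 3.90 (SD, n = 2). Alas2, the erythroid form of the first enzyme of the pathway, stood at 1284 ± 65.9 and Alas1, the ubiquitous form, at 30.6 ± 1.35. Fech stood at 559 ± 5.05 and Urod at 478 ± 32.9 TPM. Erythroid transcription factors had a median of 25.1 ± 0.042, with Klf1 at 351 ± 6.89, Nfe2 at 184 ± 9.89, Lmo2 at 111 ± 1.88, Gata1 at 91.2 ± 3.10 and Zfpm1 at 6.53 ± 0.771.

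Among other blood lineages, neutrophil genes were the most abundant, with a median of 202 ± 16.1 TPM. S100a8 stood at 3145 ± 54.0, S100a9 at 1553 ± 31.7, Ngp at 590 ± 108, Mpo at 372 ± 0.035 and Csf3r at 4.46 ± 0.608. Macrophage and Kupffer cell genes had a median of 32.3 ± 2.5 (SD, n = 2), with Lyz2 at 627 ± 29.6, C1qb at 119 ± 6.94, Vcam1 at 93.9 ± 1.24, Cd5l at 73.6 ± 2.04 and Siglec1 at 1.41 ± 0.233. Megakaryocyte genes had a median of 10.9 ± 0.559, with Pf4 at 215 ± 2.81, Ppbp at 124 ± 10.7, Itga2b at 27.0 ± 2.87, Gp9 at 23.0 ± 0.891 and Selp at 0.89 ± 0.30. Stem and progenitor genes had a median of 3.73 ± 0.198, with Lyl1 at 39.1 ± 0.877, Spi1 at 15.3 ± 0.905, Kit at 12.7 ± 0.219, Cd48 at 10.0 ± 0.764 and Hoxa9 at 0.21 ± 0.15 TPM. Lymphoid genes were lower. The B lymphoid list had a median of 2.00 ± 0.332, and the pre-B receptor genes Igll1, at 18 ± 1.59, and Vpreb1, at 12 ± 1.75, and Cd79a, at 10.7 ± 2.04, and Cd79b, at 10.3 ± 0.537, led it, while Dntt stood at 0.010 ± 0.014. The T and NK cell list had a median of 0.29 ± 0.028, with Nkg7 at 11.5 ± 0.714, Gzma at 3.95 ± 1.40, Lck at 2.75 ± 0.064, Klrb1c at 0.60 ± 0.099 and Cd3e at 0. The mast cell list had a median of 0.58 ± 0.0071, with Hdc at 6.41 ± 0.354, Cpa3 at 2.20 ± 0.255, Ms4a2 at 0.81 ± 0.25, Cma1 at 0.58 ± 0.0071 and Mcpt4 at 0.095 ± 0.13.

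Other liver cell types were described by stromal, endothelial, mesothelial and bile duct lists. Stellate and mesenchymal genes had a median of 17.6 ± 0.148 TPM, with the collagens Col3a1 at 101 ± 11.8, Col1a1 at 67.5 ± 14.5 and Col1a2 at 41.4 ± 6.83, Dcn at 54.3 ± 3.90 and Hand2 at 0.46 ± 0.092. All 15 endothelial genes were at 1 TPM or more in both libraries, with a median of 7.89 ± 0.693, Egfl7 at 46.3 ± 1.79, Stab1 at 25.8 ± 3.87, Eng at 24.2 ± 1.94, Lyve1 at 22.5 ± 0.120 and Emcn at 2.27 ± 0.184. The mesothelial list had a median of 1.85 ± 0.085, with Upk3b at 4.30 ± 0.587, Gpm6a at 2.38 ± 0.078, Msln at 2.24 ± 0.064, Upk1b at 1.46 ± 0.233 and Lrrn4 at 0.78 in both. The list of cholangiocytes, the epithelial cells of bile ducts, had a median of 1.49 ± 0.877, with Spp1 at 19.6 ± 3.0, Prom1 at 12.7 ± 0.467, Krt19 at 5.39 ± 4.09, Epcam at 3.25 ± 3.53 and Cftr at 0.055 ± 0.035.

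Cell cycle genes were expressed throughout. The 11 S phase genes had a median of 115 ± 6.03 TPM, with Rrm2 at 381 ± 23.2, Pcna at 201 ± 34.0, Mcm6 at 172 ± 6.32 and Ccne1 at 55.9 ± 6.26. The 9 mitosis genes had a median of 109 ± 8.18, with Cdk1 at 229 ± 12, Ccna2 at 196 ± 6.70, Ccnb1 at 174 ± 16.8 and Bub1 at 25.7 ± 0.686. Replication-dependent histone genes, whose copies share reads, had a median of 7.52 ± 1.12 TPM over 67 members. Hist1h2ap stood at 3740 ± 186, Hist1h4d at 434 ± 66.9, Hist1h2bc at 326 ± 24.0 and Hist1h4m at 0. Ribosomal protein genes had a median of 371 ± 36.7, with Rpl41 at 1911 ± 99.2, Rps19 at 944 ± 96.4, Rpl32 at 922 ± 111 and Rpl10l at 0. Immediate early and heat shock genes, which often mark tissue handling, had a median of 6.13 ± 1.86. Dusp1 stood at 21.3 ± 1.85, Ier2 at 16.5 ± 1.79, Ier3 at 15.5 ± 2.35 and Hspa1b at 0.035 ± 0.021.

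By RNA class, mitochondrially encoded genes held 2.21% ± 0.012 of TPM (SD, n = 2). mt-Atp6 led them, followed by mt-Atp8 at 3770 ± 145 and the ribosomal RNA mt-Rnr2 at 2293 ± 412 TPM, and mt-Ty stood at 0, as a transfer RNA too short to hold counts in these tables. Of the 37 genes 22 were below 1 TPM in both libraries, and the median was 0. Ribosomal protein genes held 3.44% ± 0.299, histones 0.566% ± 0.048 and structural and nuclear noncoding RNA 2.24% ± 0.210, where the median member stood at 86.1 ± 14.3 TPM, Malat1 at 1360 ± 22.3 and Terc at 0.30 ± 0.33. Malat1 spans chromosome 19, 5795690 to 5802672, but its TPM rests on a length of 518 nt and so depends on short transcript models. Pseudogenes held 2.85% ± 0.0043, long noncoding RNA 0.743% ± 0.0012 and spike-ins 4.52% ± 0.788. The SDs of the pseudogene and mitochondrial shares do not cover how shared reads were divided, and Gm28437 and mt-Atp6 had counts that were not whole. Of expected counts, pseudogenes held 1.23% ± 0.0048 and long noncoding RNA 1.15% ± 0.011. Of expected counts, spike-ins took 2.5% in replicate 1 and 3.19% in replicate 2. As a share of counts in place of TPM, globins held 16.1% ± 0.492 and other protein-coding genes 74.3% ± 0.275.

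Most genes with several annotated transcripts had 1 that held at least 50% of the gene. Among 4387 genes at 10 TPM or more in both libraries with several annotated transcripts, the leading transcript held a median of 74.0% ± 0.353 of the gene's TPM (SD, n = 2). It held 50% or more in 3470 genes and 90% or more in 1339, and in 372 genes it was not annotated as protein coding. In 224 genes (5.11%) the leading transcript differed between the libraries, and its median share there was 38.7%. The 6 most abundant genes whose leading transcript differed or held under 50% were Eif1, where Eif1-202, a noncoding processed transcript, held 47.9% ± 0.832, Oaz1, where Oaz1-205 held 46.8% ± 0.453, Serpinc1, where Serpinc1-205 held 49.1% ± 0.190, Ucp2, where Ucp2-209 held 34.8% ± 1.47, Cyb5a, where Cyb5a-201, annotated as a target of nonsense-mediated decay, held 47.1% ± 0.181, and Rpl38, where Rpl38-201 held 43.0% ± 1.47. Only for Serpinc1 among these 6 did the leading transcript differ between libraries. Many of these transcripts are short or partial models, and their shares depend on how shared reads were divided.

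The replicates were compared to show how far pools of the same tissue and stage differed. Genes of pancreas, intestine and skeletal muscle were higher in replicate 2, and Y-linked genes were lower. All 9 pancreas genes measured were higher in replicate 2, with a median centred log2 ratio of 1.82 (TPM + 1), as were all 9 skeletal muscle genes (1.12), all 5 intestine genes (0.58) and all 5 adrenal and gonad genes (0.59). These medians lay at or above the 99.99th percentile of matched random lists. Adding 1 to TPM shrinks the ratios of genes near or below 1 TPM. In replicates 1 and 2 the median level over all listed members was 0.19 and 1.42 TPM for intestine and 0.61 and 2.06 for adrenal and gonad. The sex-linked list stood at -0.96, with 4 of 5 genes lower. Everything below on ratios sets 1 library against 1, without a replicate check.

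The 8 named genes with the largest ratio towards replicate 2 were of digestive tract and pancreas or present at a few counts in replicate 1. Genes whose TPM intervals overlapped, some with larger ratios, were left out of these 8. Apoa4, an apolipoprotein gene of intestine and liver (ENSMUSG00000032080.6, chromosome 9, 46240696 to 46243459), had 4.29 and 985 expected counts in replicates 1 and 2, and Lypd8 (ENSMUSG00000013643.9, chromosome 11, 58379043 to 58390728) had 6 and 475. Cym, the gene of the stomach protease chymosin (ENSMUSG00000046213.9, chromosome 3, 107211293 to 107221732), had 3 and 328 counts, a depth-scaled ratio of 100.3 with a 95% counting interval of 34.0 to 489. Ckmt1 (ENSMUSG00000000308.10, chromosome 2, 121357714 to 121363737) had 1 and 218, a ratio of 200.02 with an interval of 35.5 to 7936, while its deposited TPM intervals, 0.155 to 0.623 and 3.75 to 5.57, lie closer together. Ins2, the insulin gene (ENSMUSG00000000215.6, chromosome 7, 142678656 to 142743381), stood at 0.90 and 18.9 TPM. The pancreatic enzyme genes Ctrb1 (ENSMUSG00000031957.5, chromosome 8, 111686519 to 111691010), at 6.69 and 50.8 TPM, and Cela2a (ENSMUSG00000058579.5, chromosome 4, 141814962 to 141826160), at 1.63 and 12.3 TPM, and the colipase gene Clps (ENSMUSG00000024225.4, chromosome 17, 28558149 to 28560766), at 8.53 and 50.7 TPM, completed the 8. Their centred log2 ratios ran from 2.32 for Cela2a to 3.66 for Apoa4.

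**Figure D2:**
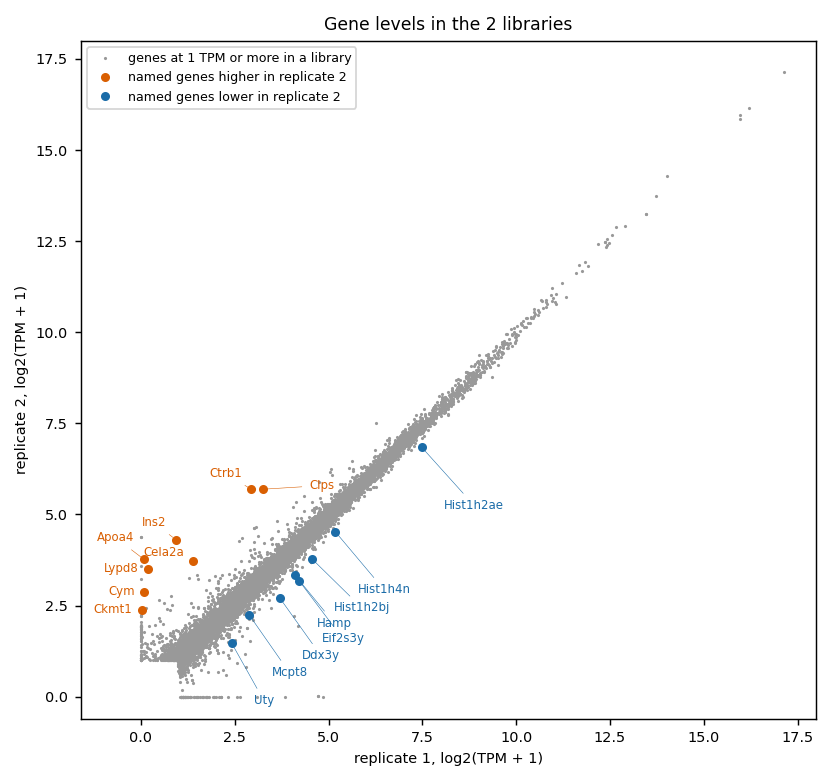
Level of each gene in replicate 1 (x axis) and replicate 2 (y axis), both as log2(TPM + 1), for genes at 1 TPM or more in either library. The 8 named genes higher and the 8 lower in replicate 2 are labelled, with Ctrb1 at 6.69 and 50.8 TPM and Eif2s3y at 17.5 and 8.10 TPM.

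Of the neighbouring-tissue lists, only skeletal muscle had a median at 10 TPM or more in both libraries (19.4 ± 11.3). The medians were 4.67 ± 5.34 for pancreas, 0.81 ± 0.87 for intestine, 1.33 ± 1.03 for adrenal and gonad and 1.18 ± 0.410 for heart. In skeletal muscle the actin gene Acta1 stood at 129 ± 74.8 TPM (SD, n = 2), Mylpf at 62.7 ± 18.4, Ckm at 32.0 ± 17.9, Tnni2 at 25.7 ± 14.2 and Myod1 at 0.46 ± 0.28. In the pancreas list Ctrb1 stood at 28.7 ± 31.2, Ins2 at 9.88 ± 12.7, Cela2a at 6.95 ± 7.53, Cpa1 at 5.46 ± 5.15 and Pnlip at 0. In the intestine list Fabp2 stood at 10.8 ± 5.02, Chga at 1.59 ± 0.424, Vil1 at 1.01 ± 0.580, Cdh17 at 0.83 ± 0.91 and Cdx2 at 0.075 ± 0.11. In the adrenal and gonad list Cyp21a1 stood at 2.45 ± 2.60, Cyp11a1 at 1.92 ± 0.863, Cyp17a1 at 1.87 ± 0.269, Star at 1.11 ± 0.757 and Nr5a1 at 0.14 ± 0.071. In the heart list Actc1, which fetal skeletal muscle also expresses, stood at 51.1 ± 27.0, Tnnt2 at 4.18 ± 1.43, Myl7 at 3.99 ± 0.311, Myh7 at 1.18 ± 0.410 and Nppa at 0.030 ± 0.042. All genes of the lung (median 0.010 ± 0.014), nervous system (0.085 ± 0.035) and kidney (0.025 ± 0.021) lists were below 1 TPM in both libraries. The lung genes were Sftpc at 0.41 ± 0.14, Sftpa1 at 0.14 ± 0.064 and Sftpb at 0.010 ± 0.014, with Nkx2-1 and Scgb1a1 at 0. Nervous system genes had Tubb3 at 0.43 ± 0.18, Stmn2 at 0.32 ± 0.15 and Sox10 at 0.080 ± 0.042, with Elavl3 lowest at 0.0050 ± 0.0071. Kidney genes had Cdh16 at 0.080 ± 0.042, Nphs1 at 0.065 ± 0.035, Slc34a1 at 0.035 ± 0.035 and Six2 at 0.010, with Umod at 0.

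The 8 named genes with the largest ratio towards replicate 1 comprised 3 Y-linked genes, 3 histone genes, Hamp and Mcpt8. Genes whose TPM intervals overlapped, some with larger ratios, were again left out of these 8. Eif2s3y (ENSMUSG00000069049.7, chromosome Y, 1010543 to 1028847) stood at 17.5 TPM in replicate 1 and 8.10 in replicate 2, a log2 ratio of -1.04. Ddx3y (ENSMUSG00000069045.7, chromosome Y, 1260771 to 1286629) stood at 12 and 5.53 (-1.01), and Uty (ENSMUSG00000068457.10, chromosome Y, 1096861 to 1245759) at 4.34 and 1.78 (-0.96). The fourth Y-linked gene of the list, Kdm5d, stood at 2.10 and 1.02 TPM, and Xist, the RNA of the inactive X chromosome, at 7.03 and 13.1. The sex-linked list had a median of 6.28 ± 1.06 TPM. Over both libraries Eif2s3y averaged 12.8 ± 6.68, Xist 10.1 ± 4.27, Ddx3y 8.78 ± 4.59, Uty 3.06 ± 1.81 and Kdm5d 1.56 ± 0.764 TPM (SD, n = 2). Hamp, the gene of the iron hormone hepcidin (ENSMUSG00000050440.7, chromosome 7, 30942368 to 30944032), stood at 16.1 and 9.15 TPM, a log2 ratio of -0.77. Mcpt8, a protease gene of basophils (ENSMUSG00000022157.7, chromosome 14, 56082166 to 56085273), stood at 6.38 and 3.75 (-0.65). The histone genes Hist1h2bj (ENSMUSG00000069300.3, chromosome 13, 22043214 to 22043676), Hist1h4n (ENSMUSG00000069305.3, chromosome 13, 21831767 to 21832196) and Hist1h2ae (ENSMUSG00000069272.5, chromosome 13, 23570517 to 23571220) had ratios of -0.78, -0.67 and -0.66, and their copies share reads.

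Smaller shifts, all relative to the median gene, ran through whole lists. Plasma transport proteins (median 0.16, 16 of 18 higher in replicate 2), complement and acute phase genes (0.17, 13 of 17), bile acid genes (0.16, 12 of 12) and coagulation factors (0.10, 15 of 17) lay above the central 95% of random lists, although each turned sign when scaled to the spike-ins. The same held for apolipoproteins (0.10), gluconeogenesis (0.11), fatty acid oxidation (0.12), blood growth factors (0.14), megakaryocyte (0.16), neutrophil (0.07), macrophage (0.10), stellate (0.20), imprinted (0.08) and immediate early genes (0.19). Cholangiocyte genes (0.21) also lay above it and stood at 0.012 when scaled to the spike-ins. Their members Krt19 and Epcam were among the genes with a ratio of 1 or more, with those of pancreas and muscle. The call of blood growth factors ended with a pseudocount of 0.1 (96.8th percentile), TMM factors (95.15th) and the spike-ins (94.7th), and that of imprinted genes with TMM factors (95.1st). Of 85 ribosomal protein genes 81 were lower in replicate 2 (median -0.20), as were 54 of 61 histone genes (-0.32), and these lists, structural RNA (-0.22) and mast cell genes (-0.18) lay below the central 95%. The call of mast cell genes ended with the spike-ins (3.72nd percentile) and after a fit on gene length and GC content (7.36th), and that of structural RNA with posterior mean TPM (5.56th). All 20 cell cycle genes were lower, but their medians (S phase -0.14, mitosis -0.12) lay at the 5.05th and 14.0th percentiles. Red cell (-0.04), haem synthesis (-0.04), erythroid transcription factor (0.02), hepatocyte transcription factor (0.10), urea cycle (0.07), cytochrome P450 (0.15), cholesterol (0.03), fetal (0.04), iron (-0.03), stem cell (-0.00), B lymphoid (0.15), T and NK (0.04), endothelial (0.08), mesothelial (0.00) and mitochondrially encoded genes (-0.03) lay inside the central 95%. After the fit on gene length and GC content, S phase (-0.16, 0.37th percentile), mitochondrially encoded (0.14, 99.99th), B lymphoid (0.17, 99.2nd) and cytochrome P450 genes (0.15, 98.5th) lay outside it. In all, 24 of 41 lists lay outside it, 19 above and 5 below. Scaled to the spike-ins the median gene moved to -0.29, which turned the sign of 14 of these lists. Relative to that median the 14 kept their sign, with values from 0.04 to 0.25.

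**Figure D3:**
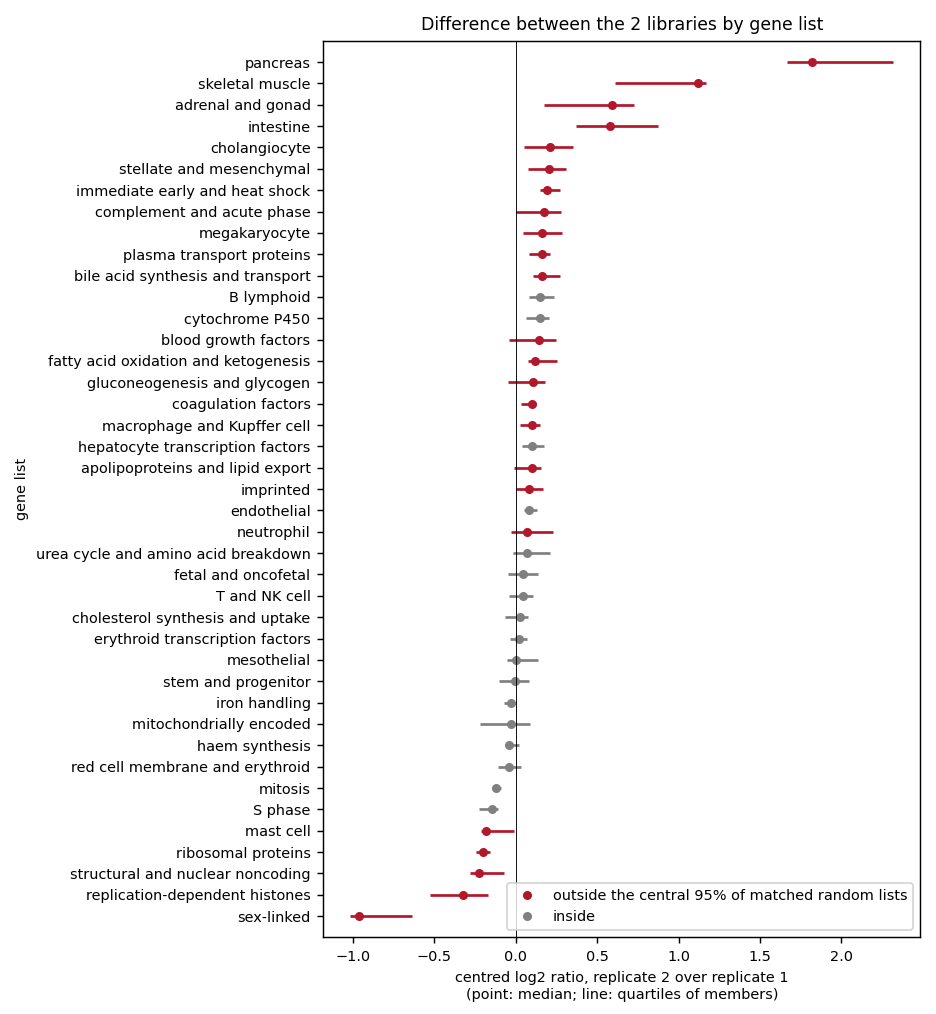
Centred log2 ratio of replicate 2 over replicate 1 on the TPM + 1 scale for 41 gene lists, with the median of members as a point and their quartiles as a line. Pancreas (1.82) and skeletal muscle (1.12) lie highest and the sex-linked list (-0.96) lowest, red marks lists outside the central 95% of matched random lists, and 14 of these with smaller medians turn sign when scaled to the spike-ins.

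Across all genes the libraries were close. Over 12843 genes at 1 TPM or more in either library, the correlation across genes of log2(TPM + 1) was 0.988 (Pearson) and 0.987 (Spearman), where genes are not independent replicates. Among 12017 genes with a mean expected count of 100 or more, 50 had a centred ratio of 1 or more in size, 46 higher and 4 lower in replicate 2, and 98.1% lay within 0.5. The split was 26 higher and 9 lower when scaled to the spike-ins, 81 and 16 at a mean count of 10 or more, and 121 and 81 with no filter. Of the 46, 6 belonged to the pancreas list and 5 to the skeletal muscle list, and of the 4 lower, Eif2s3y and Ddx3y were Y-linked and Rpl35a-ps4 and Rpl10-ps1 were pseudogenes whose intervals overlapped (these last 2 were named after their values were seen). TPM intervals did not overlap for 3051 genes (25.4%), 43 of them among the 50. Counts of the libraries differed far beyond sampling noise (chi-square 271537 with 17782 degrees of freedom), so they are not copies of 1 library.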

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

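The depth, paralog and X and Y copy tests and the other count filters for further genes were chosen after the results they address were seen, and the other tests before. The stricter reading of the X-linked partner test below was not the one written before. The design holds 1 group, so no biological explanation was tested on groups. Rules for samples far from their group and for differences between groups cannot apply to 2 libraries of 1 group.

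The numbered rows of the tables, which no comparison used, held 35.98 expected counts in replicate 1 and 29.55 in replicate 2, above the 3 counts that an empty class allows. These lay on 6 and 7 rows, and only 63 of the 26248 rows are longer than 99 nt and could hold counts.

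Pancreas, intestine and muscle genes were higher in replicate 2, which may reflect tissue carried over at dissection. Reads shared between paralogs are argued against, as the 9 members of the pancreas list with whole counts (within 0.01) stood at 1.82. The depth test cannot decide, as TPM is already scaled to a fixed sum and spike-in scaling multiplies every gene of a library by 1 factor. That scaling moved the median gene to -0.29 and left the list at 1.56. Of 22 further pancreas genes, written down before their values were seen, 12 had a mean count of 10 or more. Among them 11 were higher and 1 lower, with a median log2 ratio of 1.02, past the 0.6 that carried-over pancreas predicted. The 8 with 10 or more counts in replicate 1 also passed it (0.87), whereas all 22, of which 10 had a mean count under 10, stood at 0.45. Further stomach and intestine genes (8 of 8 higher, 0.35) and muscle genes (18 of 18 higher, 0.43) lay, like those of pancreas, above all matched random lists. Only 4 of these 8 stomach and intestine genes had 10 or more counts in replicate 1 (all higher, 0.48). Of all 16 listed, 13 were higher (0.34). For muscle, all 17 with 10 or more counts in replicate 1 (0.44) and all 20 listed (0.40) were higher. The medians of both lists under each filter fell between the bounds set in advance, 0.3 and 0.6. Only 4 of the 16 stomach and intestine genes and 7 of the 20 muscle genes listed reached 1 TPM in replicate 1. Below that level adding 1 to TPM shrinks a ratio, so the bounds cannot decide these sources, which stay open. In replicate 2 the most abundant genes of the fixed pancreas list were Ctrb1 at 50.8 TPM and Ins2 at 18.9 TPM, beside Clps outside it at 50.7 TPM.

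Y-linked genes were lower and Xist higher in replicate 2, with TPM ratios from 0.41 to 0.49 and of 1.86. Reads shared between X and Y copies are argued against, as the counts of the 4 Y-linked genes were whole numbers (largest distance 0.0). A smaller share of males in the replicate 2 pool could account for the pattern. It predicted a median above 0 for the 4 X-linked partners. The median was 0.15, at the 98.1st percentile of matched random lists, with 3 genes higher and Ddx3x lower at -0.06. The prediction as written was thus met. A stricter reading that all 4 be higher, adopted later, was not met. The 4 genes come from 1 library against 1, so a smaller share of males fits the written prediction but is not settled.

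Plasma protein genes were higher and ribosomal protein and histone genes lower in replicate 2, relative to the median gene. A straight-line trend with log2 gene length and GC content is argued against as the whole cause, while a bias of another shape was not tested. After a fit on both (R squared 0.049), the median residual was -0.17 for ribosomal proteins, -0.33 for histones and 0.19 for plasma transport proteins, each outside the central 95% of matched random lists. S phase and mitosis genes together, inside it before the fit (-0.12, 4.28th percentile), stood at -0.14 after it (0.21st), where S phase genes alone lay outside (-0.16, 0.37th) and mitosis genes alone inside (-0.11, 9.88th). A later stage of the replicate 2 pool may also give this pattern. Further late hepatic genes had a median log2 ratio of 0.23, with 19 of 20 higher, at the 100th percentile of matched random lists. They exceeded plasma transport proteins by only 0.066 (bootstrap SE 0.046), below the 0.1 set in advance. The bootstrap resampled the genes of each list, which are not independent, so its SE does not cover differences between pools. A later stage stays open, as does a different mix of cells, which was not tested.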

How the results depend on the processing

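Against 12097 expressed genes, the alternatives gave 16786 at 0.1 TPM, 8079 at 5 TPM and 14352 with posterior mean TPM, all within 1.5 times. Lists with a median of 10 TPM or more numbered 25, and 30 as TMM-scaled counts, shifted lists numbered 22 to 25 against 24, and the correlations moved by less than 0.05. Leaving out a replicate cannot move a mean of 2 libraries by 1 SD, so that alternative says nothing about stability. No paired analysis was possible because there is 1 group. The causes of the changes below were not tested, except that shares of counts are not divided by transcript length.

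Embryonic globins held 0.048% of globin with posterior mean TPM, 0.054% with expected counts and 0.118% with Hba-a1 and Hbb-bs as the only adult globins. Alpha globins held 55.1% with counts and 46.4% with single copies, and adult globins 16.1% and 13.8% of all. H19 to Igf2 was 1.40 with counts. As shares of counts, mitochondrially encoded genes held 1.62% (2.33% of posterior mean TPM), histones 0.228%, ribosomal proteins 1.94%, spike-ins 2.85% and structural RNA 0.460%. Genes differing between replicates numbered 78 with a pseudocount of 0.1, 97 at a mean count of 10 or more, 202 with no filter and 79 with DESeq2 size factors. The median leading transcript share was 71.2% at 1 TPM or more, 84.8% at 100 TPM or more, 71.5% with posterior mean TPM and 82.3% among protein-coding transcripts, and the leading transcript differed in 770 genes at 1 TPM and 15 at 100 TPM.

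Scaling to the spike-ins moved the median gene to -0.29 and turned 14 lists: plasma transport proteins -0.18, apolipoproteins -0.24, coagulation -0.23, complement -0.15, gluconeogenesis -0.18, bile acid -0.12, fatty acid oxidation -0.17, blood growth factors -0.17, megakaryocyte -0.14, neutrophil -0.26, macrophage -0.23, stellate -0.042, imprinted -0.19 and immediate early genes -0.059. Among other list shifts across the alternatives, 176 kept their side of the central 95%, 6 moved outside it (B lymphoid in 3 alternatives, cytochrome P450 in 2, urea cycle in 1) and 5 moved inside it (blood growth factors in 2, imprinted, mast cell and structural RNA in 1 each). Of list levels, 69 moved by 1 SD or more and 166 did not, but the 166 include 47 without replicate 1 and 47 without replicate 2, which could not move. As TMM-scaled counts, which are not divided by length, 41 of 47 moved, among them apolipoproteins from 595 to 268, cholesterol synthesis from 78.6 to 224 and erythroid transcription factors from 25.1 to 107. Of levels of single genes, 130 moved by 1 SD or more and 778 did not, but the 778 include 227 without replicate 1 and 227 without replicate 2, which could not move. Depth limits genes below the 3-count floor.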

Other observations

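In gene families chosen after the data were seen, some with members in the fixed lists, 1 member held most of the TPM of the members summed. The sums over glucose transporters, carbonic anhydrases and peroxide-removing enzymes left out other members of these families. Ldha held 99.3% ± 0.035 (SD, n = 2) of the lactate dehydrogenase subunits, at 1838 ± 91.2 TPM. The glucose transporter Slc2a1 held 81.4% ± 0.410 of the transporters summed and Slc2a2, the main transporter of adult hepatocytes, 10.3% ± 0.346. Pkm held 59.2% ± 0.745 of pyruvate kinase TPM and Pklr, the form of liver and red cells, 40.8% ± 0.745.

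Among other families chosen in the same way, Ccnd3 held 91.2% ± 0.559 of D-type cyclin TPM, Sod1 95.9% ± 0.281 of the superoxide dismutases, Car2 91.6% ± 0.258 of the carbonic anhydrases summed and Mt1 81.6% ± 0.716 of the metallothioneins. Gpx1, at 5280 ± 109 TPM, held 60.0% ± 0.172 of the peroxide-removing enzymes summed.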
